A study of Mus musculus with 63 samples.

How the data were processed

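The deposited values are log ratios of 2 dyes per spot on arrays of mouse oligonucleotides, each array centred near 0 by the authors, with medians from −0.072 to 0.067. Their scaling or normalization is not given in the sources used here. That the deposited ratio is in log2 is an assumption from its spread (values from −9.374 to 10.78, SD per array 0.753 to 1.75), so every log2 difference rests on it. Per the labels' protocols, total RNA extracted with Trizol was labelled indirectly with Cy3 or Cy5 and set against universal mouse reference RNA carrying the other dye, and 12 arrays carry the reversed dye order. Background correction, spot filtering and scanner settings are not given either.

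From these values the following was computed. Ratios were turned to sample over reference by the sign of each array's correlation with the median of the arrays labelled forward. As a check, 19 keratinocyte genes then lay above 22 genes of the reference pool by 1.675 to 6.305 on all 63 arrays. The turn disagreed with the labels on 2 arrays, repeats 3 and 4 of KO ras with AG1478, whose correlations with that median were −0.830 and 0.805. Of 28049 probes, 20925 mapped to 1 symbol (14541 genes), 159 to several and 6965 to none, and 19384 had a value on every array. Arrays held 24860 to 28047 values. The 2 WT mock arrays labelled repeat 1 (correlation 0.890; the most alike WT mock pair reached 0.925) were averaged, giving 62 samples. Nothing beyond the series' design statement, which names biological replicates with 1 reversed dye order, says that samples came from separate cultures. The p-values then measure only the spread between these samples, which may be technical.

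Differences were fitted in limma 3.58.1 (R 4.3.3, statmod 1.5.0; Python 3.11.15 and matplotlib 3.10.9) on all 13 groups with a term for dye order, empirical Bayes moderation and Benjamini-Hochberg adjustment over the probes of each comparison, with a threshold of 0.05. A probe was tested where at least 60 percent of the arrays of every group compared held a value. The design had 19 comparisons of 1 contrast and 3 F tests among inhibitors. Experiment numbers in the labels, parted wherever the gap exceeds 100, form 8 runs, whose meaning is not given. Runs 1 and 2 hold every WT mock group and WT ras. Run 3 holds KO ras 1 to 3, and run 4 KO mock. Runs 5 and 6 hold erlotinib in ras cells with the other KO ras arrays. Run 7 holds 3 arrays of WT ras with AG1478, and run 8 the remaining AG1478 and PD153035 arrays of ras cells. Runs are shared within ras in WT, inhibitors in WT mock, erlotinib in KO ras, and KO minus WT with each inhibitor. Among inhibitors in ras cells, AG1478 and PD153035 share run 8. Where every group compared shares runs, run was also fitted as a fixed block. Run as a random block used the consensus correlation of 0.260 between arrays of a run.

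Genes for the text were chosen by a rule set before the data were examined. It takes the probe with most values per symbol, and among called genes whose samples do not overlap between the groups, the largest changes in each direction, 10 for the 4 comparisons of genotype or ras without inhibitor and 5 for the others. It adds called members among the leading genes of each list and *Egfr*. Clone or locus codes were skipped. The 25 gene lists, 5 of them markers of other cell types, were also written beforehand. Each was tested with limma's cameraPR at a preset correlation of 0.01 and again with the correlation estimated from residuals, adjusted over the lists of a comparison. The fit was tried on simulated data with 100 probes changed by each size. For log2 changes of 1 and 2 it recovered 14 and 81 percent in ras effect in WT, 4 and 64 percent in ras effect in KO, 13 and 72 percent in PD153035 in WT mock, and 4 and 78 percent in KO minus WT in ras with PD153035. False calls were 6.86, 1.45, 7.61 and 3.53 percent, leaving out run effects, which were not simulated.

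Alternatives set before the data were examined were: no dye term, forward arrays only, the repeat 1 arrays kept apart, median centring, quantile normalization, probes with a value on every array, no filter, a fit with only the groups compared, probes averaged by gene, run as fixed or random block, replicate number as block, controls split between profiles, an estimated list correlation, and each sample left out. Chosen after seeing the data were array weights, sign and dye term by label, dye term by label, both disputed arrays left out, run as random block for single inhibitors against each other and between genotypes, the means over 3 inhibitors and over AG1478 with erlotinib, and profiles without shared samples. Each comparison's samples were also regrouped in up to 100 other splits of the same sizes. No file or column was left out.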

Results

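Keratinocytes from newborn mice with (WT) or without (KO) functional EGFR were mock-treated or transduced with v-rasHa, and some cultures then received an EGFR kinase inhibitor, AG1478, erlotinib or PD153035, at 1 µM for 2 h, per the labels' protocols. Each array set 1 sample against a reference RNA pooled from mouse cell lines. The 63 arrays form 13 groups and 62 samples: 5 per group, except 4 for WT mock and KO ras with erlotinib, 3 for KO mock and 6 for KO ras with AG1478. Brackets hold log2 differences ± SE and the adjusted p of limma, and the log base is assumed. Turned to sample over reference, ratios of keratinocyte genes lay above those of reference pool genes on all 63 arrays. Experiment numbers fall into 8 runs. Where groups of different runs are compared, the count with run as a random block stands beside the main count.

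*Egfr*, the targeted gene, was read by 2 probes, and neither was called in a comparison. Array weights and sign and dye term by label each gave 1 call. In mock cells the probes gave −0.60 ± 0.49 (adjusted p = 0.533) and −1.15 ± 0.58 (adjusted p = 0.291) in KO minus WT. In ras cells they gave 0.34 ± 0.40 (adjusted p = 0.716) and −0.63 ± 0.48 (adjusted p = 0.537). The first probe averaged 2.58 in WT mock, 2.01 in WT ras, 1.99 in KO mock and 2.35 in KO ras. The second averaged 1.85, 1.21, 0.70 and 0.59 in the same groups. Where the probes lie relative to the deleted part is not given in the sources used here, so these values check no genotype label.

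Transduction of WT cells raised the viral sequence, and few named host genes were called, with low power for log2 changes of 1. Of 27 probes assigned to retroviral gag, 14 rose, and the median over all 27 was 2.10. *Epor*, the erythropoietin receptor (2.71 ± 0.41, 2.92e-05), rose. So did *Kcnd1*, a potassium channel subunit (2.72 ± 0.58, 0.0126), and *Krt23*, a type I keratin (2.47 ± 0.56, 0.0313). *Ptpn22*, a lymphoid phosphatase (1.72 ± 0.38, 0.0171), and *Myo5b*, an unconventional myosin (1.64 ± 0.39, 0.0459), also rose. *Bend7* rose (1.41 ± 0.32, 0.0331) while its other probe had the opposite sign. *Foxd3*, a neural crest transcription factor (−1.61 ± 0.31, 0.00283), and the olfactory receptor *Olfr1093* (−2.33 ± 0.48, 0.00956) fell. Cholesterol and fatty acid synthesis genes rose together under the preset correlation, with 21 of 21 members positive (median 0.42, adjusted p = 0.000134 and adjusted p = 0.196 with an estimated correlation). Suprabasal differentiation genes did likewise, 22 of 28 positive (median 0.68, adjusted p = 0.0275 and adjusted p = 0.578 with an estimated correlation). Fibroblast markers (19 members, median −0.73, adjusted p = 8.58e-05) and TGF-beta target genes (12 members, median −0.40, adjusted p = 0.00487) fell together. Both calls were lost on re-estimation (adjusted p = 0.554 and adjusted p = 0.0871). No member of these 4 lists was called over all genes. When adjusted over the list alone, 2 fibroblast markers and 1 TGF-beta target fell. The ras effect in WT held 51 called probes, 49 higher and 2 lower. Run as a random block gave 60, and single left-out samples 34 to 57.

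In the transduction of KO cells, *Prl2c5* (5.85 ± 0.83, 1.42e-05) and *Prl2c2* (5.35 ± 1.08, 0.00414), proliferin genes of the prolactin family, rose most. KO mock, 3 arrays alone in run 4, stood apart in both: *Prl2c5* averaged 0.70 there and 3.13 to 7.51 in every other group, *Prl2c2* 0.80 and 3.90 to 7.37, untransduced WT mock included. *F10*, coagulation factor X (1.83 ± 0.39, 0.00853), and the glutathione transferase *Gsto1* (1.46 ± 0.37, 0.0393) rose too. *Dlk1*, a membrane protein of the EGF-like Notch ligand family (−3.96 ± 0.39, 3.93e-10), and *Cd320*, the transcobalamin receptor (−3.44 ± 0.44, 1.52e-06), fell. *Pou3f1*, a POU-domain transcription factor (−3.21 ± 0.72, 0.0139), fell with the keratins *Krt84* (−3.20 ± 0.48, 6.21e-05) and *Krt15* (−2.94 ± 0.46, 0.000151). Lower too were the skin chemokine *Ccl27a* (−2.93 ± 0.62, 0.00743), the collagen chain *Col1a2* (−2.69 ± 0.66, 0.0344) and the laminin-binding *Bcam* (−1.47 ± 0.35, 0.0236). Further falls were *Anp32b* (−2.84 ± 0.59, 0.00535), *Cyb5r3* (−2.42 ± 0.42, 0.000592) and *Cyp2c37* (−2.38 ± 0.48, 0.00399). The other probes of *Anp32b* and *Cyb5r3* had the opposite sign. Of the 27 gag probes, 4 rose. Fibroblast markers fell together, 1 of 19 members called and 4 adjusted over the list alone (median −0.71, adjusted p = 4.75e-05 and adjusted p = 0.657 with an estimated correlation). Proliferation genes rose together, 28 of 37 positive, 0 called and 0 adjusted over the list alone (median 0.43, adjusted p = 0.0123 and adjusted p = 0.657 with an estimated correlation). The ras effect in KO held 151 called probes, 25 higher and 126 lower. KO ras and KO mock share no run, and run as a random block left 7 calls. Leaving out 1 sample gave between 41 (without KO mock replicate 1) and 282 (without KO mock replicate 2), with 5 of 8 left-out samples moving the count by over 1.5 times.

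**Figure D1:**
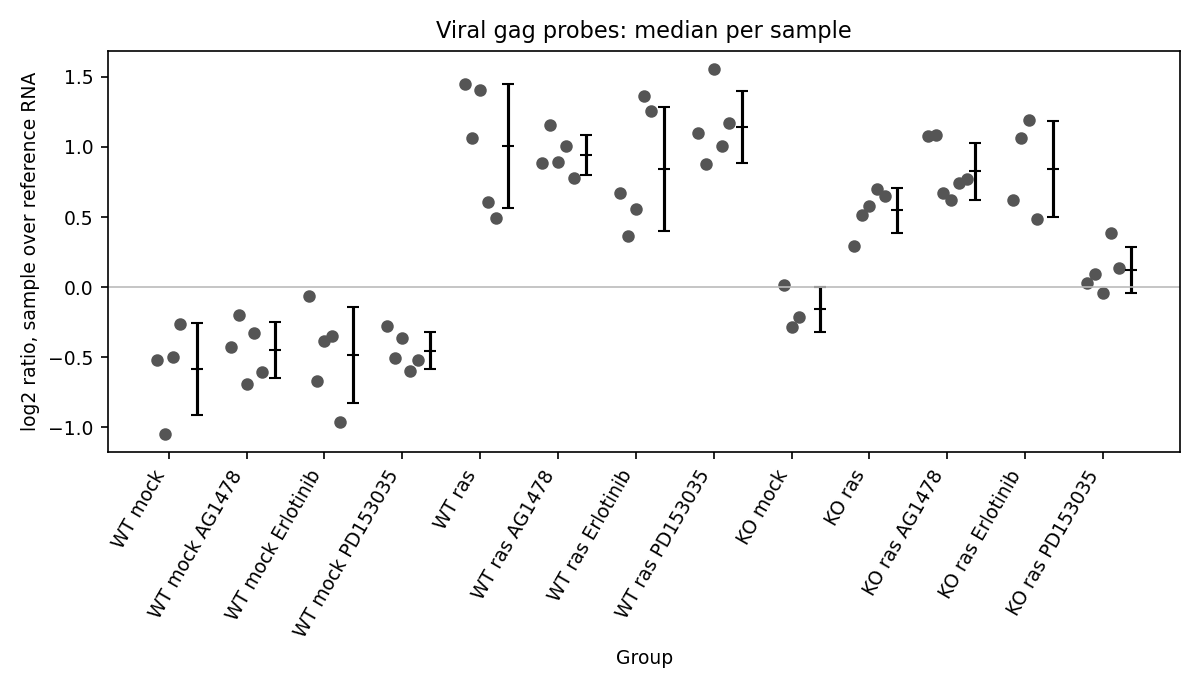
Median log2 ratio of the gag probes, sample over reference RNA, by group. Each point is 1 sample, and the bar beside a group is its mean and SD.

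The ras response differed between genotypes at 3 probes, all with a lower response in KO: *Dlk1* (−4.01 ± 0.52, 9.64e-06), *Cd320* (−3.22 ± 0.60, 0.023) and *Cyp2c37* (−3.28 ± 0.63, 0.0315), named after their values were seen. *Dlk1* averaged 3.08 in KO mock and −0.88 to −0.23 in the 12 other groups, so its difference rests on the KO mock arrays. Both genotypes shared 14 probes higher with ras, against 0.0440 for independent lists, and gag was the only named gene among them. Among the lists, p53 target genes had a higher response in KO under the preset correlation, 0 of 16 members called and 0 adjusted over the list alone (adjusted p = 0.0393 and adjusted p = 0.545 with an estimated correlation). For ras effect KO minus WT, a random block for run left 1 call. Without KO mock replicate 2 the count was 50, without WT mock replicate 3 it was 1, and 9 of 17 left-out samples moved it by over 1.5 times.

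In mock-treated cells *Egr1*, an immediate early transcription factor induced by ERK signalling (−2.39 ± 0.35, 6.61e-05), was lower in KO than in WT. So were *Ptgs2*, cyclooxygenase 2 (−4.81 ± 1.12, 0.024), the neutrophil chemokine *Cxcl1* (−3.67 ± 0.86, 0.024) and the alarmin *S100a9* (−2.69 ± 0.65, 0.0257). *Prl2c2* (−5.25 ± 1.13, 0.0104) and *Prl2c5* (−4.75 ± 0.86, 0.00194) were lower too. The hyaluronan receptor *Cd44* was lower (−4.87 ± 1.19, 0.0284), and its 8 other probes were negative and not called. Also lower were the elongation factor *Eef2* (−2.86 ± 0.75, 0.0396), *Hspd1* (−2.77 ± 0.56, 0.00636), *Acot7* (−2.68 ± 0.63, 0.024), *Ppp1r37* (−2.76 ± 0.46, 0.000628) and *Pkm* (−1.24 ± 0.33, 0.0447). Higher in KO were keratins of basal and differentiating layers, *Krt15* (3.13 ± 0.48, 0.000136), *Krt14* (3.09 ± 0.82, 0.0447) and *Krt10* (2.37 ± 0.56, 0.0247). They were joined by *Krt6b* (2.94 ± 0.80, 0.0482) and the cornified envelope gene *Sprr1a* (2.65 ± 0.70, 0.042). *Dlk1* (3.46 ± 0.40, 3.24e-07) and the BMP and Wnt modulator *Sostdc1* (3.16 ± 0.78, 0.03) were higher as well. So were *Ccl27a* (2.72 ± 0.65, 0.0255) and *Id2*, an inhibitor of helix-loop-helix factors (1.80 ± 0.40, 0.0161). Higher too were *Spag17* (3.79 ± 0.77, 0.00658), *Sycp2* (3.77 ± 0.98, 0.0392), *Tex29* (3.61 ± 0.91, 0.0336), *Ms4a13* (3.37 ± 0.89, 0.042), *Tspan8* (3.32 ± 0.87, 0.04) and *Nap1l5* (3.06 ± 0.78, 0.0364).

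By list, in mock cells, proliferation genes were lower in KO in 34 of 37 members (median −0.98, 0 called, 10 adjusted over the list alone, adjusted p = 7.89e-10 and adjusted p = 0.0813 with an estimated correlation). Cytokines and chemokines were lower (1 of 22 rose, 2 fell, 1 and 8 adjusted over the list alone, median −1.10, adjusted p = 2.62e-05 and adjusted p = 0.0667 with an estimated correlation). ERK pathway target and feedback genes were lower (1 of 29 fell, 6 adjusted over the list alone, median −0.50, adjusted p = 0.000256 and adjusted p = 0.272 with an estimated correlation). Basal keratinocyte genes were higher (2 of 18 rose and 1 fell, 7 rose and 1 fell adjusted over the list alone, median 0.90, adjusted p = 0.00319). In 19 of 21 members, cholesterol and fatty acid synthesis genes were lower (0 called, 0 adjusted over the list alone, median −0.43, adjusted p = 0.00319). Each of these lists had adjusted p = 0.302 with an estimated correlation. Hypoxia and glycolysis genes were lower (1 of 20 fell, 2 rose and 6 fell adjusted over the list alone, median −0.11, mean −0.47, adjusted p = 0.0227 and adjusted p = 0.302 with an estimated correlation). Endothelial markers were positive in 9 of 9 members (0 called, 2 rose adjusted over the list alone, median 1.31, adjusted p = 0.023 and adjusted p = 0.443 with an estimated correlation). KO minus WT in mock held 310 called probes, 188 higher and 122 lower. The groups share no run, and run as a random block left 5 calls. Single left-out samples gave between 64 (without KO mock replicate 3) and 473 (without KO mock replicate 2), 6 of 7 moving the count by over 1.5 times.

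Among ras-transduced cells, immediate early genes were lower in KO: *Egr1* (−3.30 ± 0.29, 1.68e-11), *Fos* (−2.45 ± 0.62, 0.0279), and *Dusp1*, a MAP kinase phosphatase (−1.75 ± 0.45, 0.0295). *Fosb* was lower (−1.25 ± 0.32, 0.0287) with its other probe of opposite sign. Inflammatory transcripts were lower with them, *Il24* (−3.06 ± 0.81, 0.0336), *Csf2* (−2.05 ± 0.54, 0.0324), *S100a9* (−2.05 ± 0.54, 0.0318) and *S100a8* (−2.03 ± 0.58, 0.0493). So were genes of DNA replication and the cell cycle, *Mcm4* (−2.44 ± 0.61, 0.0279), *Ccne1* (−2.02 ± 0.49, 0.0227), *Mcm7* (−1.73 ± 0.43, 0.0271) and *Birc5* (−1.62 ± 0.39, 0.0228). *Cdkn1a*, the cell cycle inhibitor p21, was higher (1.84 ± 0.46, 0.027). Sterol synthesis genes *Nsdhl* (−1.63 ± 0.43, 0.0367), *Cyp51* (−1.39 ± 0.29, 0.00705) and *Sqle* (−1.09 ± 0.30, 0.0394) were lower. Other large falls were *Sprr2j-ps* (−4.01 ± 1.01, 0.0279), *Wfdc2* (−3.31 ± 0.66, 0.00516), *Sprr2i* (−2.96 ± 0.69, 0.0226) and *Lrrc40* (−2.61 ± 0.72, 0.0426, other probe of opposite sign). They extended to *Pabpc1* (−2.41 ± 0.52, 0.0105), *Samsn1* (−2.26 ± 0.49, 0.0108) and *Cyp2c37* (−2.26 ± 0.42, 0.00382). *Hspd1* (−2.05 ± 0.46, 0.0143) and *Irf9* (−1.29 ± 0.36, 0.0428) were also lower. Higher in KO were *Sostdc1* (2.89 ± 0.65, 0.0129), *H2-M10.4* (2.65 ± 0.48, 0.00355), *Pp2d1* (2.36 ± 0.63, 0.0352) and *Aste1* (2.16 ± 0.55, 0.0279). Next were *C1qtnf12* (1.99 ± 0.50, 0.027), the glyoxalase *Glo1* (1.87 ± 0.31, 0.00141) and the Wnt modulator *Dact2* (1.75 ± 0.36, 0.00705). Then came the metalloprotease inhibitor *Timp3* (1.72 ± 0.34, 0.00512), *Spon2* (1.71 ± 0.37, 0.0103) and the creatine transporter *Slc6a8* (1.67 ± 0.40, 0.0219). *Dst*, a hemidesmosome plakin (1.5 ± 0.33, 0.0109), *Id2* (1.45 ± 0.33, 0.0156) and *Notch1* (1.19 ± 0.33, 0.0424) were higher too.

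Cholesterol and fatty acid synthesis genes were lower in KO ras cells as a list, 20 of 21 negative, 3 called and 9 adjusted over the list alone (median −0.66, adjusted p = 1.37e-07 and adjusted p = 0.0424 with an estimated correlation). Proliferation genes were lower, 35 of 37 negative, 6 called and 10 adjusted over the list alone (median −0.68, adjusted p = 2.84e-09 and adjusted p = 0.0718 with an estimated correlation). Of ERK pathway target and feedback genes 26 of 29 were negative and the list lower, 5 called and 6 adjusted over the list alone (median −0.57, adjusted p = 2.49e-06 and adjusted p = 0.0718 with an estimated correlation). Cytokines and chemokines were lower, 2 of 22 called and 4 adjusted over the list alone (median −1.03, adjusted p = 0.00159 and adjusted p = 0.128 with an estimated correlation). KO minus WT in ras held 537 called probes, 215 higher and 322 lower. Of the 27 gag probes, 3 were lower and 0 higher. No sample is shared with the mock comparison, and the 2 sets of differences correlated at 0.524. Among called probes, 32 were higher in both (1.45 for independent lists) and 22 lower in both (1.41 for independent lists). Both comparisons set WT samples of runs 1 and 2 against KO samples of runs 3 to 6, so neither the correlation nor the overlap separates genotype from run. Run as a random block left 1 call. Left-out samples gave 83 to 1008, 7 of 10 moving the count by over 1.5 times.

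In WT mock cells the inhibitors left every single gene short of the threshold, while proliferation genes and cytokines shifted down as lists. Proliferation genes were negative in 31 of 37 members with AG1478 (median −0.30, adjusted p = 0.000151 and adjusted p = 0.549 with an estimated correlation). They were negative in 35 of 37 with erlotinib (median −0.50, adjusted p = 1.82e-08 and adjusted p = 0.145 with an estimated correlation) and 35 of 37 with PD153035 (median −0.60, adjusted p = 1.89e-12 and adjusted p = 0.0272 with an estimated correlation). Cytokines and chemokines, 22 members, fell together with AG1478 (median −0.80, adjusted p = 3.94e-05 and adjusted p = 0.0591 with an estimated correlation). They did so with erlotinib (median −0.66, adjusted p = 1.36e-05 and adjusted p = 0.0506 with an estimated correlation) and PD153035 (median −0.88, adjusted p = 1.62e-07 and adjusted p = 0.00794 with an estimated correlation). With AG1478, ERK pathway target and feedback genes fell together under the preset correlation (adjusted p = 0.0339 and adjusted p = 0.59 with an estimated correlation). So they did with erlotinib (adjusted p = 0.0491 and adjusted p = 0.714 with an estimated correlation) and PD153035 (23 of 29 negative, median −0.36, adjusted p = 4.73e-05 and adjusted p = 0.125 with an estimated correlation). Leukocyte and Langerhans cell markers moved up beside these, 12 of 14 positive with AG1478 (adjusted p = 0.0103 and adjusted p = 0.549 with an estimated correlation). Positive were 14 of 14 with erlotinib (adjusted p = 0.0011 and adjusted p = 0.399 with an estimated correlation) and 14 of 14 with PD153035 (adjusted p = 0.00159 and adjusted p = 0.246 with an estimated correlation). Endothelial markers were positive in 9 of 9 with AG1478 and with PD153035 (smallest adjusted p = 0.303 with an estimated correlation). Hypoxia and glycolysis genes fell with erlotinib and PD153035 under the preset correlation alone, as did proteases, inhibitors and matrix remodelling genes and TGF-beta target genes with PD153035 (smallest adjusted p = 0.123 with an estimated correlation). Adjusted over the list alone only 1 proliferation gene fell, with AG1478.

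In the same WT mock cells, limma called 0 probes for AG1478, erlotinib and PD153035, with 1813, 889 and 958 at unadjusted p under 0.05. Array weights, chosen after seeing the data, gave 27, 6 and 293. The median 95% interval reached 0.797, 0.796 and 0.792 either side of the estimate, so smaller changes of single genes are not excluded. The F test of differences among the 3 inhibitors called 0 probes (limma; 581 at unadjusted p under 0.05), as did each pair (869, 866 and 326 for AG1478 minus erlotinib, AG1478 minus PD153035 and erlotinib minus PD153035).

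In WT ras cells *Egr1* fell with AG1478 (−2.61 ± 0.29, 7.17e-08), erlotinib (−2.78 ± 0.29, 9.36e-09) and PD153035 (−2.79 ± 0.29, 8.34e-09). *Btg2*, an antiproliferative immediate early gene, fell with each (−1.46 ± 0.36, 0.0213; −1.70 ± 0.36, 0.00419; −2.22 ± 0.36, 0.000612). So did *Ms4a2*, a chain of the IgE receptor (−3.30 ± 0.68, 0.00806; −3.31 ± 0.68, 0.00438; −3.85 ± 0.68, 0.00185). *Id2* rose with each (2.10 ± 0.33, 0.000278; 2.30 ± 0.33, 4.74e-05; 1.92 ± 0.33, 0.00118). So did *Ndrg1*, a gene induced by hypoxia and differentiation (1.66 ± 0.36, 0.0101; 1.96 ± 0.36, 0.00113; 1.96 ± 0.36, 0.00199). Across the 3 inhibitors, set against the same 5 control samples, 22 probes were higher and 12 lower each time.

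AG1478 in WT ras raised *Ak3*, a mitochondrial adenylate kinase (3.77 ± 0.65, 0.000908), *Cyp2a5* (3.06 ± 0.61, 0.00441), *St8sia2* (2.92 ± 0.61, 0.00786), *Aste1* (2.79 ± 0.55, 0.0043), *Kmt5a* (2.63 ± 0.64, 0.0213) and *Krt7* (2.12 ± 0.45, 0.00906). Further rises were in *Sprr1a* (2.02 ± 0.58, 0.0487) and the phosphatase *Dusp4* (1.71 ± 0.46, 0.0351). Its smaller rises were in *Timp3* (1.69 ± 0.34, 0.00492), *Ddit3* (1.45 ± 0.36, 0.0224), *Vldlr* (1.36 ± 0.34, 0.0237) and *Mvd* (1.20 ± 0.30, 0.0266). It lowered *Pax9* (−3.31 ± 0.90, 0.0404), *Cckar* (−2.58 ± 0.71, 0.041), *Cnot2* (−2.30 ± 0.42, 0.00195), *Hspd1* (−1.97 ± 0.46, 0.0182), *Tpi1* (−1.79 ± 0.43, 0.02) and *Cd3g* (−1.76 ± 0.50, 0.0468). So were *Mcm7* (−1.54 ± 0.43, 0.0452), *Klf6* (−1.53 ± 0.28, 0.00228), *Asns* (−1.40 ± 0.37, 0.0343) and *Hk2* (−1.10 ± 0.31, 0.0471). Other probes of *Tpi1* and *Asns* had the opposite sign. Erlotinib in WT ras raised *Morn3* (4.92 ± 0.84, 0.000473), *Emilin2* (4.53 ± 0.72, 0.000149), the serpin *Serpinb11* (4.15 ± 1.07, 0.0221), *Elf2* (3.79 ± 0.65, 0.000485), *St8sia2* (3.77 ± 0.61, 0.000185) and *Sprr2f* (2.50 ± 0.70, 0.0352). It also raised *Krt7* (2.01 ± 0.45, 0.00837), *Timp3* (1.67 ± 0.34, 0.00319), *Col6a2* (1.65 ± 0.49, 0.047) and *Car9* (1.10 ± 0.32, 0.0395). It lowered *Il24* (−3.22 ± 0.81, 0.0175), *Ccne1* (−2.23 ± 0.49, 0.00622), *Mycl* (−2.21 ± 0.55, 0.0163), *Ppp3cb* (−2.19 ± 0.57, 0.0233), *Mcm4* (−2.14 ± 0.61, 0.0382), *Hspd1* (−1.94 ± 0.46, 0.0134) and *Ccng1* (−1.91 ± 0.45, 0.0125). It also lowered *Csf2* (−1.80 ± 0.54, 0.0469), *Mcm3* (−1.54 ± 0.34, 0.00685), *Klf6* (−1.43 ± 0.28, 0.00259) and *Vegfa* (−1.32 ± 0.40, 0.0497). PD153035 in WT ras raised the lipid droplet gene *Plin1* (3.61 ± 0.59, 0.000612), *Tex22* (3.25 ± 0.70, 0.013), *Lrrc46* (3.20 ± 0.77, 0.0321), *Slc13a3* (3.00 ± 0.71, 0.0262), *Aste1* (2.79 ± 0.55, 0.00503) and *Ddit3* (1.62 ± 0.36, 0.0159). It lowered *Sprr2i* (−3.82 ± 0.64, 0.00118), *Ccl12* (−3.59 ± 0.85, 0.0277), *Rasgrp1* (−2.58 ± 0.54, 0.00843) and *Fos* (−2.56 ± 0.62, 0.0321).

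ERK pathway target and feedback genes fell as a list in WT ras with AG1478 (1 of 29 rose and 2 fell, 2 rose and 6 fell adjusted over the list alone, median −0.31, adjusted p = 0.00268 and adjusted p = 0.668 with an estimated correlation). With erlotinib they fell as well (2 of 29, 3 adjusted over the list alone, median −0.55, adjusted p = 0.00191 and adjusted p = 0.631 with an estimated correlation) and with PD153035 (2 fell, 1 rose and 4 fell adjusted over the list alone, median −0.35, adjusted p = 0.000646 and adjusted p = 0.401 with an estimated correlation). Proliferation genes fell with AG1478 (1 of 37 called, 2 adjusted over the list alone, adjusted p = 0.00268 and adjusted p = 0.668 with an estimated correlation). With erlotinib they fell too (3 of 37 called, adjusted p = 0.00191 and adjusted p = 0.631 with an estimated correlation). With AG1478, simple epithelial keratins rose (1 of 7 called, 7 positive, adjusted p = 0.014 and adjusted p = 0.668 with an estimated correlation). Suprabasal differentiation genes rose (1 of 28 called, 2 adjusted over the list alone, adjusted p = 0.014 and adjusted p = 0.786 with an estimated correlation), and cytokines and chemokines fell (0 of 22 called, adjusted p = 0.0291 and adjusted p = 0.668 with an estimated correlation). With PD153035, basal keratinocyte genes fell (0 called, 1 adjusted over the list alone, adjusted p = 0.0262 and adjusted p = 0.636 with an estimated correlation). Members of the p53 target list fell together (1 of 16 called, adjusted p = 0.0262 and adjusted p = 0.401 with an estimated correlation), and cytokines and chemokines fell (0 called, 4 adjusted over the list alone, adjusted p = 0.0415 and adjusted p = 0.536 with an estimated correlation).

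In WT ras, AG1478 called 539 probes (249 higher, 290 lower), erlotinib 950 (634 higher, 316 lower) and PD153035 184 (129 higher, 55 lower). The control group shares no run with any of them, and run as a random block left 1, 26 and 1 calls. Single left-out samples gave 129 to 961, 243 to 1523 and 55 to 359 in the same order.

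Set against each other in WT ras, AG1478 and PD153035 differed most in called probes. *Krt17* (3.58 ± 0.94, 0.0397), *Tcf21* (3.23 ± 0.75, 0.0213) and *Sprr3* (3.19 ± 0.73, 0.0209) were higher with AG1478. The basement membrane collagen *Col4a3* (−2.97 ± 0.69, 0.0213), *Hook1* (−2.72 ± 0.59, 0.0162) and *Apoe* (−2.66 ± 0.52, 0.00668) were lower. Suprabasal differentiation genes were higher with AG1478 than with PD153035 (3 of 28 called, 5 adjusted over the list alone, adjusted p = 0.00279 and adjusted p = 0.983 with an estimated correlation). The pairs gave 357 probes for AG1478 minus PD153035, 249 for AG1478 minus erlotinib and 49 for erlotinib minus PD153035 (16, 0 and 0 with run as a random block in limma), and the F test 460. The inhibitor groups lie in different runs, except that 2 AG1478 arrays share run 8 with PD153035, and run as a random block left the F test 6 calls. It gave 184 without WT ras AG1478 replicate 1 and 859 without WT ras Erlotinib replicate 2.

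**Figure D2:**
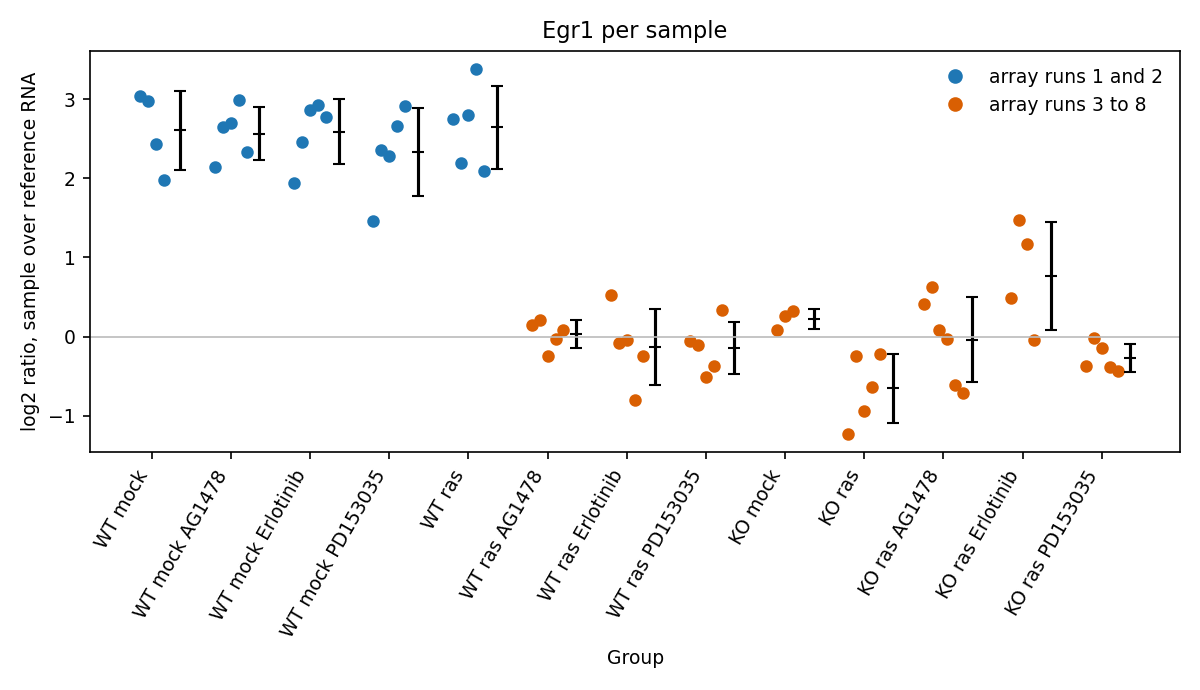
*Egr1* log2 ratio of sample over reference RNA in each group. Each point is 1 sample, set by group along the horizontal axis, and its colour parts array runs 1 and 2 from runs 3 to 8. Bars are mean and SD.

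The mean inhibitor response in WT ras differed from that in WT mock in 6 probes. *Egr1* fell more in ras cells (−2.62 ± 0.35, 2.17e-05) and *Id2* rose more (2.07 ± 0.40, 0.0318). Outside the naming rule, *St8sia2* (3.61 ± 0.74, 0.0473) and *Aste1* (3.23 ± 0.66, 0.0473) rose more, while *Zfp36l1* (−1.72 ± 0.35, 0.0473) and 1 unnamed probe (−2.23 ± 0.43, 0.0318) fell more. No list differed. For mean inhibitor effect WT ras minus WT mock, a random block for run left 1 call. Left-out samples gave 1 to 16, 21 of 39 moving the count by over 1.5 times.

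In KO ras cells, where the targeted receptor is absent per the labels, *Aldh1a3*, a retinaldehyde dehydrogenase, rose with AG1478 (2.70 ± 0.50, 0.0129) and erlotinib (3.08 ± 0.55, 0.012). AG1478 also raised the glutamate transporter *Slc17a7* (2.35 ± 0.55, 0.0453), *Aste1* (2.30 ± 0.52, 0.0391), the taste receptor *Tas1r1* (1.98 ± 0.44, 0.0282) and *Atp9a* (1.63 ± 0.37, 0.0391). It lowered *Nyap2* (−2.43 ± 0.47, 0.015), *Rasgrp1* (−2.17 ± 0.51, 0.0457), *Erlin1* (−1.77 ± 0.41, 0.0419), *Vegfa* (−1.68 ± 0.40, 0.0457) and *Arpin* (−1.49 ± 0.32, 0.0269). With sign and dye term by label, *Vegfa* in AG1478 in KO ras was 0.29 (adjusted p = 0.797). Erlotinib raised *Dusp9* (3.75 ± 0.77, 0.0327), *Olfr1514* (3.18 ± 0.59, 0.0183), *Dock5* (2.42 ± 0.50, 0.0327), the linker histone *H1f2* (1.90 ± 0.40, 0.0327) and *Egr1* (1.43 ± 0.31, 0.048). EGF family ligands rose together with erlotinib, 0 of 5 called and 3 adjusted over the list alone (median 1.72, adjusted p = 0.0047 and adjusted p = 0.0205 with an estimated correlation). ERK pathway target and feedback genes (1 of 29 rose, 8 adjusted over the list alone, adjusted p = 6.02e-05) rose with erlotinib, as did cytokines and chemokines (0 of 22, 2 adjusted over the list alone, adjusted p = 0.00168). Each had adjusted p = 0.155 with an estimated correlation. Proliferation genes (0 of 37, 3 adjusted over the list alone, adjusted p = 0.00102), proteases, inhibitors and matrix remodelling genes (0 of 19, 2 adjusted over the list alone, adjusted p = 0.0047) and cholesterol and fatty acid synthesis genes (0 of 21, adjusted p = 0.00883) rose as well. Each had adjusted p = 0.321 with an estimated correlation. Stress keratins and alarmins rose (0 of 15, 4 adjusted over the list alone, adjusted p = 0.00312 and adjusted p = 0.255 with an estimated correlation). Endothelial markers were negative in 9 of 9 (median −0.71, adjusted p = 0.00634 and adjusted p = 0.321 with an estimated correlation). No list was called with AG1478.

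The arrays labelled KO ras with PD153035 differed most from KO ras. *Sprr2j-ps* (4.22 ± 1.01, 0.0123), *Trim66* (3.50 ± 0.69, 0.00365), *Klhdc10* (3.11 ± 0.80, 0.0174) and *Calr3* (3.09 ± 0.82, 0.0202) were higher. Also higher were *Gsg1* (2.99 ± 0.84, 0.0297), *Pfkp* (2.55 ± 0.79, 0.0483), *Hspd1* (1.98 ± 0.46, 0.0104), the mitotic kinase *Plk1* (1.81 ± 0.40, 0.00646), *Cd3g* (1.78 ± 0.50, 0.0283), *Asns* (1.41 ± 0.37, 0.0198), *Irf9* (1.40 ± 0.36, 0.0171), *Fth1* (1.18 ± 0.37, 0.0481) and *Slc3a2* (1.11 ± 0.29, 0.0178). *Prl2c5* (−3.42 ± 0.71, 0.00481), the protease *Klk8* (−3.14 ± 0.69, 0.00618), *Nfe2l3* (−3.07 ± 0.63, 0.00413) and *Cd200* (−2.62 ± 0.60, 0.00833) were lower. So were the lactate transporter *Slc16a3* (−2.59 ± 0.63, 0.0135), the ribonucleotide reductase subunit *Rrm2* (−2.58 ± 0.64, 0.0148), *Timp1* (−2.56 ± 0.67, 0.0194), *Trp63*, the p63 regulator of stratified epithelium (−2.40 ± 0.72, 0.0393), *Scd2* (−2.21 ± 0.47, 0.00529), *Mmp3* (−2.08 ± 0.59, 0.0313) and *Sox9* (−2.04 ± 0.46, 0.00767). Lesser falls were in *Ccnb2* (−1.84 ± 0.48, 0.0179), *Slc2a1* (−1.71 ± 0.46, 0.0233), *Itgb1* (−1.67 ± 0.33, 0.00337, other probe of opposite sign), *Kif11* (−1.34 ± 0.35, 0.0198), *Id3* (−1.30 ± 0.34, 0.019), *Ldha* (−1.17 ± 0.31, 0.0198), *Id1* (−1.16 ± 0.35, 0.0386) and *Id2* (−1.13 ± 0.33, 0.0366). Of the 27 gag probes 5 were lower. Basal keratinocyte genes fell (3 of 18 called, 1 rose and 7 fell adjusted over the list alone, adjusted p = 0.00374 and adjusted p = 0.367 with an estimated correlation). Cholesterol and fatty acid synthesis genes fell (3 of 21, 4 adjusted over the list alone, adjusted p = 0.00295 and adjusted p = 0.234 with an estimated correlation), as did hypoxia and glycolysis genes (1 of 20 rose and 3 fell, 1 rose and 8 fell adjusted over the list alone, adjusted p = 0.00374 and adjusted p = 0.234 with an estimated correlation). Proteases, inhibitors and matrix remodelling genes fell (2 of 19, 4 adjusted over the list alone, adjusted p = 0.0085 and adjusted p = 0.367 with an estimated correlation). Unfolded protein and amino acid stress genes rose (2 of 15, 5 adjusted over the list alone, adjusted p = 0.0315 and adjusted p = 0.234 with an estimated correlation).

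In KO ras, AG1478 called 64 probes (26 higher, 38 lower), erlotinib 15 (13 higher, 2 lower) and PD153035 1353 (723 higher, 630 lower). Run as a random block left each with 0 calls in limma, and run as a fixed block, possible only for erlotinib, left 2. Single left-out samples gave 3 to 663, 0 to 397 and 375 to 2554 in the same order. AG1478 in KO ras gave 2285 with sign and dye term by label.

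Among inhibitors in KO ras, the EGF family ligand *Hbegf* was higher with erlotinib than on the arrays labelled PD153035 by 3.36 (95% interval 2.19 to 4.53, adjusted p = 0.000262) and with AG1478 by 2.03 (0.97 to 3.09, adjusted p = 0.0453). *Egr1* (1.04, 0.42 to 1.66, adjusted p = 0.0333) and *Fosl1* (2.53, 0.97 to 4.09, adjusted p = 0.0405) were also higher with erlotinib than with PD153035. *Bnc1*, basonuclin, exceeded the PD153035 arrays with erlotinib (6.22 ± 0.96, 9.5e-05), along with *Il24* (4.55 ± 0.86, 0.000772), *Ccl20* (4.05 ± 0.79, 0.00104) and *Cd200* (3.89 ± 0.63, 0.000143). *Tex33* (−4.60 ± 1.04, 0.0047), *Hils1* (−3.95 ± 0.99, 0.0106) and *Npas2* (−3.56 ± 0.59, 0.000181) were below them. Lists higher with erlotinib than with PD153035 under either correlation were cholesterol and fatty acid synthesis (8 of 21 called), hypoxia and glycolysis (8 of 20), cytokines and chemokines (7 of 22), TGF-beta targets (4 of 12) and EGF family ligands (2 of 5), each with adjusted p = 0.0133 with an estimated correlation. Proteases, inhibitors and matrix remodelling genes did so too (7 of 19, adjusted p = 0.0144 with an estimated correlation). With an estimated correlation, TGF-beta targets (3 of 12, adjusted p = 0.00031), cholesterol and fatty acid synthesis genes (3 of 21, adjusted p = 0.00377) and hypoxia and glycolysis genes (1 of 20, adjusted p = 0.0298) were higher with AG1478 than with PD153035. Unfolded protein and amino acid stress genes (1 of 15, adjusted p = 0.00377) and FOXO targets (0 of 12, adjusted p = 0.0133) were lower by that test. The pairs gave 1608 probes for erlotinib minus PD153035, 208 for AG1478 minus PD153035, which share run 8, and 67 for AG1478 minus erlotinib. With run as a random block in limma they gave 6, 384 and 0. *Xist*, which follows sex, was lower with erlotinib than with AG1478 (adjusted p = 0.0351) and PD153035 (adjusted p = 0.000149). The sex of the cells is not given in the sources used here, so sex is not excluded from these differences. The F test called 1066, and 280 with run as a random block. It gave 483 without KO ras Erlotinib replicate 3 and 1496 without KO ras Erlotinib replicate 4.

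The mean response to inhibitors differed between WT ras and KO ras. *Egr1* (−3.54 ± 0.34, 3.01e-10), *Klf6* (−1.45 ± 0.33, 0.0427) and *Hspd1* (−2.34 ± 0.54, 0.0433) fell more in WT ras, as did *Btg2* (adjusted p = 0.0254), and *Id2* rose more (2.43 ± 0.38, 0.000632). Outside the naming rule, the death receptor *Tnfrsf10b* (−2.59 ± 0.42, 0.00112) fell more and *Pdcd4* (1.39 ± 0.25, 0.00742), *Ecm1* (2.23 ± 0.45, 0.0254) and *Psca* (2.76 ± 0.59, 0.032) rose more. ERK pathway target and feedback genes fell more (2 of 29 called, 4 adjusted over the list alone, adjusted p = 3.79e-05 and adjusted p = 0.343 with an estimated correlation). The same was seen for proliferation genes (0 of 37, adjusted p = 0.00302 and adjusted p = 0.663 with an estimated correlation) and cytokines and chemokines (0 of 22, adjusted p = 0.0482 and adjusted p = 0.59 with an estimated correlation). Fibroblast markers had the opposite direction, 17 of 19 positive (0 called, adjusted p = 0.0482 and adjusted p = 0.92 with an estimated correlation). Simple epithelial keratins rose more (0 of 6, 2 adjusted over the list alone, adjusted p = 0.0189 and adjusted p = 0.544 with an estimated correlation). For mean inhibitor effect WT ras minus KO ras, 51 probes were called, 16 higher and 35 lower. Inhibitor by inhibitor, AG1478 gave 245, erlotinib 18 and PD153035 26 (1, 1 and 4 with run as a random block). Run as a random block left 1 call and sign and dye term by label 8. Left-out samples gave 6 to 553, 24 of 40 moving the count by over 1.5 times.

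With AG1478 present, *Klk6* (−3.79 ± 0.81, 0.00511), *Krt78* (−3.42 ± 0.57, 0.000406), *Nyap2* (−3.31 ± 0.50, 0.000155), *Psca* (−3.31 ± 0.49, 0.000103) and *Serpina11* (−3.19 ± 0.53, 0.000406) were lower in KO ras than in WT ras cells. *Kprp* (−2.80 ± 0.78, 0.0395), the heme oxygenase *Hmox1* (−2.68 ± 0.71, 0.0289), *Dusp4* (−2.42 ± 0.44, 0.00086) and *Krt7* (−1.94 ± 0.43, 0.00789) followed. Also below WT were *Ndrg1* (−1.76 ± 0.34, 0.00207), the urokinase receptor *Plaur* (−1.75 ± 0.51, 0.0488), *Ccne1* (−1.69 ± 0.47, 0.0362), *Defb4* (−1.62 ± 0.41, 0.0193), *Nsdhl* (−1.60 ± 0.42, 0.0247), *Mvd* (−1.50 ± 0.29, 0.0019) and *Vldlr* (−1.49 ± 0.32, 0.00586). *Tuba3a* (3.65 ± 1.02, 0.0392), *Serpinb3a* (3.45 ± 0.89, 0.0232), *Apbb1* (3.18 ± 0.92, 0.0476) and the desmoglein *Dsg1a* (2.90 ± 0.82, 0.0428) were higher. So were *Sostdc1* (2.85 ± 0.62, 0.006), *Svs2* (2.80 ± 0.78, 0.0401), *Tgfbi* (2.55 ± 0.53, 0.0035), the integrin *Itga6* (1.54 ± 0.41, 0.0262), *Notch1* (1.43 ± 0.32, 0.00681), *Dst* (1.24 ± 0.31, 0.0208), *Ednrb* (1.22 ± 0.34, 0.0392) and *Pgk1* (0.89 ± 0.26, 0.0471). With sign and dye term by label, KO minus WT in ras with AG1478 turned negative for *Apbb1* (−0.07), *Dsg1a* (−0.43), *Itga6* (−0.09) and *Pgk1* (−0.09). Cholesterol and fatty acid synthesis genes were lower (3 of 21, 6 adjusted over the list alone, adjusted p = 9.54e-05 and adjusted p = 0.139 with an estimated correlation). Basal keratinocyte genes (2 of 18 rose, 3 rose and 1 fell adjusted over the list alone, adjusted p = 0.0196 and adjusted p = 0.549 with an estimated correlation) and Notch pathway genes (1 of 12, 2 adjusted over the list alone, adjusted p = 0.018 and adjusted p = 0.156 with an estimated correlation) were higher. So were TGF-beta target genes (1 of 12, 2 adjusted over the list alone, adjusted p = 0.0109 and adjusted p = 0.139 with an estimated correlation) and melanocyte markers (1 of 9, 2 adjusted over the list alone, adjusted p = 0.0104 and adjusted p = 0.156 with an estimated correlation). Suprabasal differentiation genes were lower (1 of 28 rose and 1 fell, 1 rose and 7 fell adjusted over the list alone, median −0.91, adjusted p = 0.0173 and adjusted p = 0.698 with an estimated correlation). Stress keratins and alarmins (1 of 15, adjusted p = 0.0131 and adjusted p = 0.353 with an estimated correlation) and simple epithelial keratins (2 of 7, adjusted p = 0.0227 and adjusted p = 0.421 with an estimated correlation) were lower. With sign and dye term by label the basal (adjusted p = 0.126), Notch and TGF-beta lists (each adjusted p = 0.469) turned, and with run as a fixed block the suprabasal (adjusted p = 0.295) and stress keratin lists (adjusted p = 0.623) did. The comparison held 615 called probes, 227 higher and 388 lower. *Xist* was among those higher in KO, so sex is not excluded here. Run as a random block gave 273, run as a fixed block 632, leaving out the 2 arrays whose direction disputes their labels 291, and sign and dye term by label 1677. Left-out samples gave 341 to 891, 3 of 11 moving the count by over 1.5 times.

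With erlotinib present, *Krt7* (−3.20 ± 0.48, 0.000123), the protease inhibitor *Wfdc2* (−4.03 ± 0.70, 0.000899) and *Gsta4* (−3.10 ± 0.71, 0.0201) were lower in KO ras than in WT ras cells. So were *Elf2* (−3.09 ± 0.69, 0.0169), the claudin *Cldn3* (−3.06 ± 0.63, 0.00867) and *Car9* (−1.35 ± 0.34, 0.0344). *Tnfrsf11b*, osteoprotegerin (3.25 ± 0.58, 0.00158), *Trp63* (3.22 ± 0.76, 0.0252) and *Pou3f1* (2.85 ± 0.66, 0.0214) were higher. So were *Slc16a3* (2.57 ± 0.67, 0.043), *Mst1r* (2.46 ± 0.53, 0.0127), *Lama3* (1.92 ± 0.45, 0.0225), *Itga6* (1.77 ± 0.45, 0.0369) and *Fas* (1.51 ± 0.36, 0.0274). The other probe of *Lama3* had the opposite sign. Basal keratinocyte genes were higher (3 of 18, 8 adjusted over the list alone, median 1.12, adjusted p = 2.08e-07 and adjusted p = 0.0412 with an estimated correlation). Beside them were melanocyte markers, 9 of 9 positive (0 called, 3 adjusted over the list alone, adjusted p = 0.000334 and adjusted p = 0.0405 with an estimated correlation), and also Notch pathway genes (0 of 12, 4 adjusted over the list alone, adjusted p = 0.00111 and adjusted p = 0.0405 with an estimated correlation). Proteases, inhibitors and matrix remodelling genes (0 called, 6 adjusted over the list alone, adjusted p = 0.00111 and adjusted p = 0.226 with an estimated correlation) and p53 target genes (1 of 16, 2 adjusted over the list alone, adjusted p = 0.00192 and adjusted p = 0.0623 with an estimated correlation) were higher. So were ERK pathway target and feedback genes (0 called; 2 rose and 1 fell adjusted over the list alone, adjusted p = 0.00563 and adjusted p = 0.305 with an estimated correlation) and hypoxia and glycolysis genes (1 of 20 fell, 4 rose and 3 fell adjusted over the list alone, adjusted p = 0.0359 and adjusted p = 0.305 with an estimated correlation). Simple epithelial keratins (1 of 6, 2 adjusted over the list alone, adjusted p = 0.00633 and adjusted p = 0.226 with an estimated correlation) and cholesterol and fatty acid synthesis genes (0 of 21, 4 adjusted over the list alone, adjusted p = 0.0225 and adjusted p = 0.305 with an estimated correlation) were lower. The comparison KO minus WT in ras with Erlotinib held 267 called probes, 139 higher and 128 lower. Run gave 807 calls as a fixed block and 637 as a random block. Left-out samples gave 80 to 419, 5 of 9 moving the count by over 1.5 times.

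The arrays labelled KO ras with PD153035 lay below WT ras with PD153035 in sterol synthesis, chemokine and mitotic genes. *Scd2* (−3.25 ± 0.47, 1.33e-05), *Idi1* (−2.56 ± 0.48, 0.000902), *Dhcr7* (−2.53 ± 0.39, 3.3e-05) and *Cyp51* (−1.45 ± 0.29, 0.00196), of lipid and sterol synthesis, were lower. The chemokines *Cxcl5* (−5.37 ± 1.11, 0.004), *Ppbp* (−4.38 ± 0.76, 0.000319) and the interferon-inducible *Ifi204* (−3.90 ± 0.57, 1.75e-05) were lower as well. So were the simple epithelial keratins *Krt18* (−3.35 ± 0.76, 0.012) and *Krt7* (−1.88 ± 0.45, 0.0162). Mitotic genes *Ccnb2* (−2.34 ± 0.48, 0.00302), *Cdk1* (−2.11 ± 0.41, 0.00162), *Top2a* (−2.06 ± 0.44, 0.00554) and *Bub1b* (−1.97 ± 0.40, 0.00274) had the same direction. So had *Dusp4* (−2.40 ± 0.46, 0.00115), *Etv4* (−2.36 ± 0.52, 0.00654), *Hbegf* (−2.10 ± 0.55, 0.0342) and *Btc* (−1.93 ± 0.52, 0.0434). Further falls were in *Ndrg1* (−2.93 ± 0.36, 4.54e-07), *Gsta4* (−3.24 ± 0.67, 0.00395), *Ctsl* (−2.71 ± 0.56, 0.00395), *Gsta1* (−2.15 ± 0.55, 0.0298), *Id2* (−1.59 ± 0.33, 0.00401), *Srxn1* (−1.30 ± 0.27, 0.00481) and *Ftl1* (−0.94 ± 0.24, 0.024). *Exph5* (2.63 ± 0.53, 0.00251), *Cwc22* (2.59 ± 0.54, 0.00401), *Mtm1* (2.27 ± 0.34, 1.74e-05), *Veph1* (2.26 ± 0.43, 0.00153) and *Rrp8* (2.18 ± 0.36, 0.000191) were higher. So were *Notch1* (1.40 ± 0.33, 0.0136), *Btg2* (1.38 ± 0.36, 0.0302), *Dst* (1.21 ± 0.33, 0.0421) and *Slc3a2* (1.13 ± 0.29, 0.0255). Of the 27 gag probes, 11 were lower.

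By list on the same arrays, cholesterol and fatty acid synthesis genes were lower in 21 of 21 members (8 called, 14 adjusted over the list alone, median −1.07, adjusted p = 9.69e-25 and adjusted p = 1.52e-07 with an estimated correlation). Proliferation genes (7 of 37, 1 rose and 20 fell adjusted over the list alone, median −0.88, adjusted p = 6.18e-16 and adjusted p = 0.00486 with an estimated correlation) and EGF family ligands (2 of 5, 3 adjusted over the list alone, adjusted p = 0.000727 and adjusted p = 0.00142 with an estimated correlation) were lower. So were cytokines and chemokines (1 of 22, 3 adjusted over the list alone, adjusted p = 0.000341 and adjusted p = 0.0336 with an estimated correlation) and NRF2 target genes (4 of 17, 1 rose and 6 fell adjusted over the list alone, adjusted p = 0.000727 and adjusted p = 0.0336 with an estimated correlation). FOXO target genes (0 of 12, 2 adjusted over the list alone, adjusted p = 0.00207 and adjusted p = 0.0298 with an estimated correlation) and p53 target genes (1 of 16, 2 adjusted over the list alone, adjusted p = 0.000727 and adjusted p = 0.0319 with an estimated correlation) were higher. Lost on re-estimation were the calls of simple epithelial keratins (2 of 7 lower, adjusted p = 0.00178 and adjusted p = 0.128 with an estimated correlation) and proteases, inhibitors and matrix remodelling genes (1 lower, 2 adjusted over the list alone, adjusted p = 0.00178 and adjusted p = 0.156 with an estimated correlation). So were those of hypoxia and glycolysis genes (1 lower, adjusted p = 0.00178 and adjusted p = 0.0976 with an estimated correlation), Notch pathway genes (1 higher, adjusted p = 0.0316 and adjusted p = 0.133 with an estimated correlation) and fibroblast markers (0 of 19, adjusted p = 0.0328 and adjusted p = 0.626 with an estimated correlation). ERK pathway target and feedback genes, with a median of 0.00 and a mean of −0.28, were not called (2 of 29 fell, adjusted p = 0.123). KO minus WT in ras with PD153035 held 386 called probes, 148 higher and 238 lower. *Xist* was among those higher in KO here too, so sex is not excluded. Run gave 690 calls as a fixed block and 605 as a random block. Left-out samples gave 205 to 394, 6 of 10 moving the count by over 1.5 times.

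**Figure D3:**
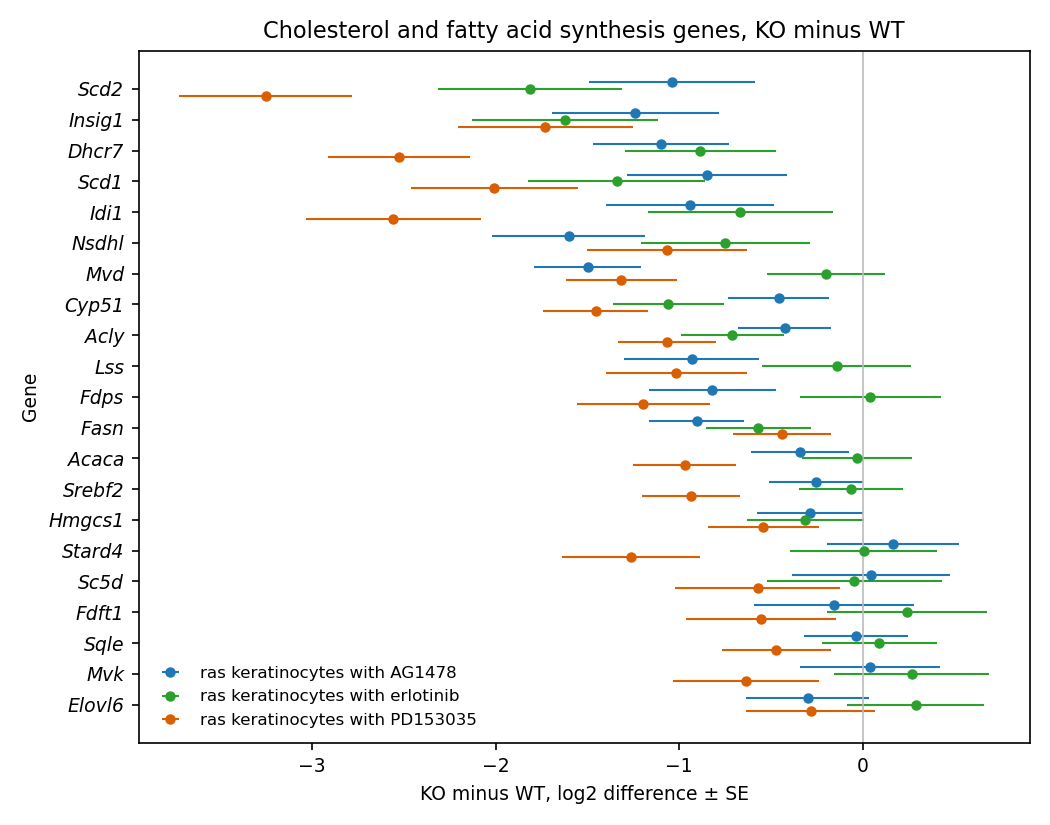
Cholesterol and fatty acid synthesis genes, KO minus WT in ras cells with each inhibitor, by gene. Points are log2 differences and bars their SE, with 1 colour per inhibitor.

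With every inhibitor, KO minus WT called 14 probes lower and 3 higher. Lower were *Krt7* (−1.94, −3.20 and −1.88), *Ndrg1*, *Psca*, *Msln*, *Ecm1*, *Anxa9*, *Aif1l*, *Sik2*, *Abcg1*, *Gpsm1*, *Lrrn4cl* and 1 gag probe (−1.38, −1.49 and −2.22). *Gstp1*, *S100a10* and *Spats2l* were higher, all named after their values were seen. Of 27 gag probes, 1, 1 and 11 were lower. The mean over the 3 inhibitors was chosen after seeing the data. In it *Krt7* (−2.34 ± 0.26, 1.75e-08), *Msln*, mesothelin (−2.27 ± 0.26, 1.78e-08), *Ndrg1* (−2.02 ± 0.21, 1.49e-09) and *Tmcc2* (−1.62 ± 0.23, 2.59e-06) were lower. *Spats2l* (1.39 ± 0.19, 1.98e-06), *Clic4* (1.38 ± 0.20, 2.25e-06), *Gpc4* (1.36 ± 0.23, 5.11e-05) and *Bzw2* (1.25 ± 0.17, 8.03e-07) were higher. Cholesterol and fatty acid synthesis genes were lower (12 of 21, 15 adjusted over the list alone, adjusted p = 1.36e-14 and adjusted p = 0.000213 with an estimated correlation). So were NRF2 target genes (6 of 17, 1 rose and 8 fell adjusted over the list alone, adjusted p = 0.00058 and adjusted p = 0.0397 with an estimated correlation). Taken singly, only PD153035 called either list by that test. Notch pathway genes (3 of 12, 4 adjusted over the list alone, adjusted p = 0.000122 and adjusted p = 0.00831 with an estimated correlation) and p53 target genes (4 of 16, 7 rose and 1 fell adjusted over the list alone, adjusted p = 0.00014 and adjusted p = 0.0174 with an estimated correlation) were higher. Melanocyte markers were too (2 of 9, 3 adjusted over the list alone, adjusted p = 0.000284 and adjusted p = 0.0307 with an estimated correlation). This mean held 1777 called probes, 819 higher and 958 lower (10 gag). It held 2463 with run as a fixed block (12 gag lower), 1225 without the PD153035 arrays and 1409 to 2061 without single samples.

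As whole profiles, KO minus WT in ras and the mean inhibitor effect in WT ras correlated at 0.452 over 19384 probes. They share 5 control samples of runs 1 and 2. Unchanged groups against shared controls gave 0.615 in simulation. With the controls split, the mean was 0.066 (−0.146 to 0.289 over 20 splits). The covariance was 0.146 against 0.102 simulated. *Egr1* was called lower and *Id2* higher in both, and neither shared controls nor run is excluded. With no sample in common, KO minus WT in mock and the mean inhibitor effect in WT ras correlated at 0.287, and both set later runs against runs 1 and 2. KO minus WT in ras and the mean inhibitor effect in WT mock correlated at 0.194. Both comparisons were chosen after seeing the data. Among the inhibitors in WT ras, erlotinib and PD153035 correlated at 0.693 (0.499 simulated, 0.299 with controls split), AG1478 and erlotinib at 0.513 (0.5002 simulated, 0.187 split) and AG1478 and PD153035 at 0.382 (0.499 simulated, 0.061 split).

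Lists never called in a comparison were ErbB receptors, with 4 members measured (smallest adjusted p = 0.145, erlotinib in WT ras), interferon response genes, 24 members (adjusted p = 0.337, erlotinib in KO ras), heat shock genes, 7 members (adjusted p = 0.212, erlotinib in KO ras), and muscle markers, 9 members (adjusted p = 0.508, ras effect in KO).

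**Figure D4:**
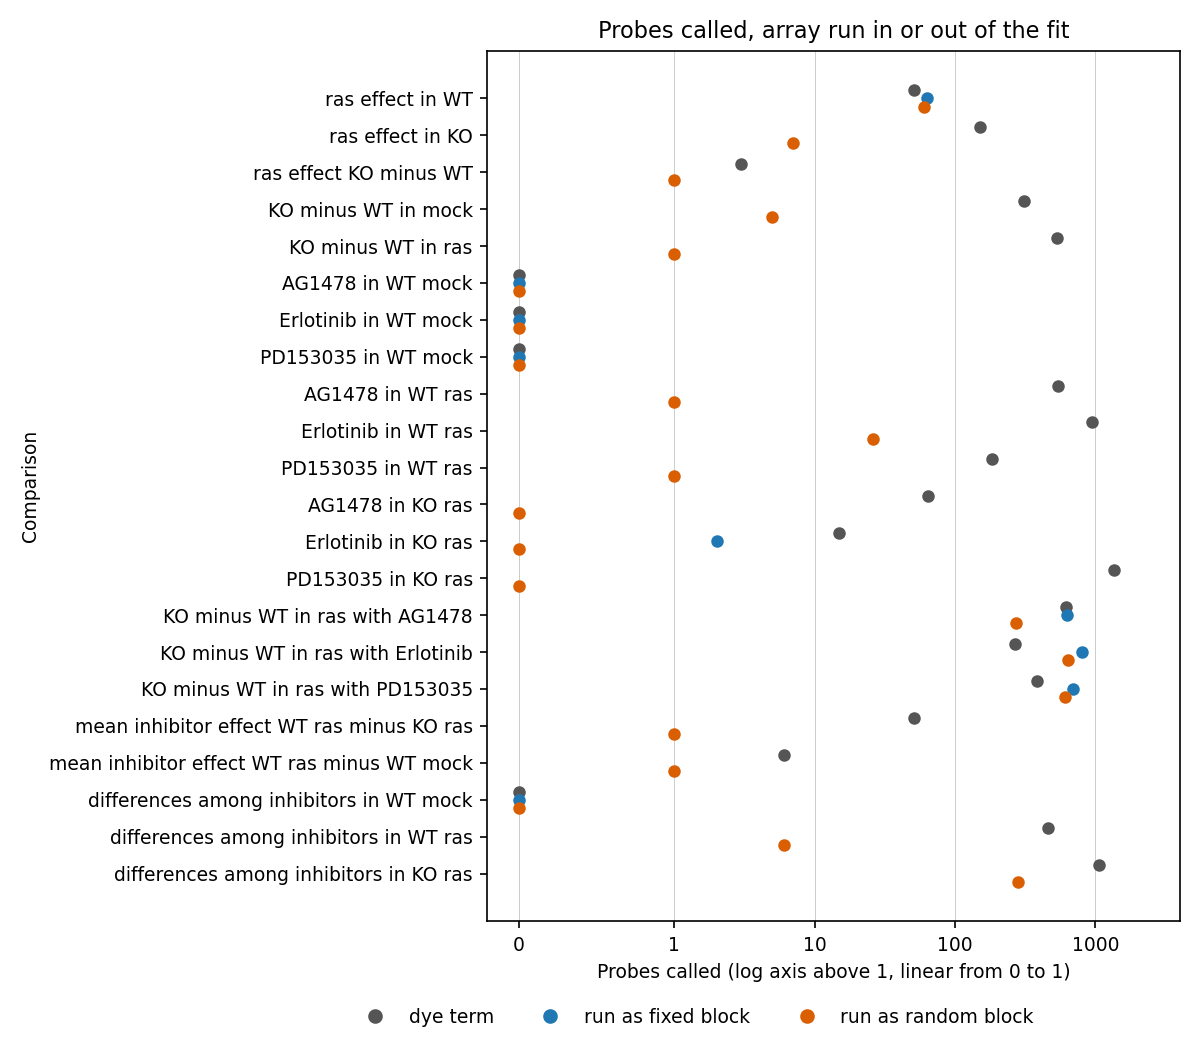
Probes called per comparison with the dye term alone and with array run as a fixed or random block. Each point is 1 count, on an axis that is linear from 0 to 1 and logarithmic above.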

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

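Chosen only after the result was seen were the tests of run and of PD153035 in WT cells for the viral signal, both later transduction tests, and both *Egr1* tests. The other tests here were written before their results, although the prediction for the first transduction test was overwritten after its result and then restored to its first wording.

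Viral gag signal on the arrays labelled KO ras with PD153035 averaged 0.12, against 0.55 in KO ras, 0.83 with AG1478, 0.84 with erlotinib and −0.16 in KO mock. Narrower ratios were excluded, since 92.3 percent of the gap was left after quantile normalization, and so was a run difference, since PD153035 lay −0.707 from AG1478 within run 8 (exact permutation p = 0.00216). Loss of the viral transcript to PD153035 in any ras keratinocyte was excluded by WT ras, where the difference was 0.139 (lower 95% bound −0.388), although these groups share no run. A loss in KO cells alone was not tested. Fewer transduced cells were tested first by the position between KO mock (0) and KO ras (100), where the group lay at 60.5 against 74.3 with AG1478 and 74.3 with erlotinib, which by its prediction spoke against that explanation, although untransduced WT mock groups lay at 54.0 to 59.4 on that axis. A later test used 32 of the non-gag probes called in the ras effect in WT. It placed the group 40.8 percent of the way from KO mock to the other inhibitor groups. Only 6 probes are named and the others may be viral sequence, so it decides nothing. Those 6, without *Bend7*, *Foxd3* and *Olfr1093*, placed the group at 35.9 percent (SE 15.1). Yet untransduced WT mock groups with inhibitor lay at 25.7 to 45.2 percent between WT mock and WT ras on them. Fewer transduced cells remain a possible hypothesis only.

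*Egr1* averaged 2.55 on the 24 samples of runs 1 and 2 (1.456 to 3.385) and −0.06 on the 38 samples of runs 3 to 8 (−1.234 to 1.476). A run difference cannot be told from group, since 0 groups have arrays on both sides. The mean inhibitor effect on *Egr1* was −0.109 in WT mock (lower 95% bound −0.629) and −2.73 in WT ras. WT mock excluded an equal fall, not a small one. Of 19384 probes with a value on every sample, 0 parted these runs without overlap. A response confined to ras cells was not tested apart from run. Every *Egr1* or *Id2* difference between early and late runs carries this limit.

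Repeats 3 and 4 of KO ras with AG1478 run against the direction their labels give. Exchanged dye labels fit: repeat 3 followed the dye profile of other groups at 0.550 and repeat 4 at −0.0814, a difference of 0.631 where forward arrays spread by 0.196. An inverted sign with right dye labels was excluded by repeat 4 (−0.0814). No biological explanation was tested.

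A sample far from the others marked 16 of 180 groups of values tested, where chance marks about 9. *Egfr* (second probe) in WT ras AG1478 had a sample at 2.75 (others −0.05 to 0.67), and *Krt10* in KO ras Erlotinib at 2.27 (1.07 to 1.28). *Ptgs2* had samples at 2.98 in WT mock PD153035 (5.75 to 6.16), 3.07 in WT ras Erlotinib (5.76 to 6.55) and 0.76 in KO ras (4.36 to 5.67). *Prl2c2* had samples at 5.56 in WT ras PD153035 (7.08 to 7.36) and 5.47 in KO ras AG1478 (6.65 to 7.20), and *Prl2c5* at 0.30 in WT mock Erlotinib (4.17 to 5.15) and 1.07 in WT mock PD153035 (3.94 to 5.02). *Tgfa* had a sample at 3.98 in WT ras AG1478 (2.32 to 2.75), and *Id2* at 0.19 in WT mock AG1478 (−1.38 to −1.13), −2.22 in WT mock Erlotinib (−1.06 to −0.69) and −0.31 in WT ras PD153035 (0.60 to 0.85). Missing spots numbered 3150 on 1 array of WT mock Erlotinib (23 to 326), 1095 in WT mock PD153035 (52 to 228) and 3189 in KO ras AG1478 (64 to 281). Differences between groups, each by a test of the difference itself, were marked for the ras effect KO minus WT (3 probes), the mean inhibitor effect WT ras minus KO ras (51) and the mean inhibitor effect WT ras minus WT mock (6).

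Regrouping asked how many splits, the real one included, give as many calls on probes with a value on every array. The splits ignore run, so they never weigh it. With over 2 groups they weigh any difference among them, not the contrast. Under 5 percent did so, which excludes chance alone, in ras effect in WT (2 of 100; real 47, highest other 51), KO minus WT in mock (1 of 35; 392, 11), AG1478 (3 of 100; 500, 1181), Erlotinib (1; 857, 479) and PD153035 (4; 163, 357) in WT ras, PD153035 in KO ras (3; 1246, 2098), KO minus WT in ras with AG1478 (1; 608, 418), Erlotinib (1; 214, 204) and PD153035 (2; 366, 646), the mean inhibitor effect WT ras minus KO ras (1; 58, 28) and WT ras minus WT mock (4; 7, 108), the F test in KO ras (1; 972, 778) and KO minus WT over the mean of 3 inhibitors (1; 1616, 20). Chance was not excluded in ras effect in KO (8 of 56; 157, 556), ras effect KO minus WT (14 of 100; 2, 79), KO minus WT in ras (6; 541, 2614), AG1478 (9; 42, 177) and Erlotinib (14; 14, 3407) in KO ras, the F test in WT ras (5; 378, 1029), and AG1478, Erlotinib, PD153035 (100 each; 0 in limma; 2, 3 and 2) and the F test (100; 0, 148) in WT mock. Splits with several times the real count point to a structure of the samples. The highest other split kept run 3 together in ras effect in KO, KO minus WT in ras and all inhibitors in KO ras, and run 7 in AG1478 in WT ras and the F test in WT ras.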

How the results depend on the processing

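Alternatives changed 1 setting at a time, but sign and dye term by label and the replicate block each change 2 terms. The cause of each move below was not tested, except that fits on fewer samples or probes have less power by construction. The counts below are probes called, and those not named stayed within 1.5 times the main count. Array weights, both settings by label and leaving out both disputed arrays were chosen after seeing the data.

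With run as a random block, counts became 7 in ras effect in KO, 1 in ras effect KO minus WT, 5 in KO minus WT in mock, 1 in KO minus WT in ras, 1, 26 and 1 for AG1478, Erlotinib and PD153035 in WT ras, 0 in limma for each in KO ras, 273, 637 and 605 in KO minus WT in ras with AG1478, Erlotinib and PD153035, 1 in each mean inhibitor effect difference, and 6 and 280 in the F tests in WT ras and KO ras. With run as a fixed block they became 2 for Erlotinib in KO ras and 807 and 690 in KO minus WT in ras with Erlotinib and PD153035, and 55 lists were called; in KO minus WT in ras with AG1478 the stress keratins (adjusted p = 0.623) and suprabasal lists (adjusted p = 0.295) reversed.

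With quantile normalization, counts became 247 in ras effect in KO, 1 in ras effect KO minus WT, 872 in KO minus WT in mock (428 higher, 444 lower), 340 for AG1478 in WT ras, 474, 0 (limma) and 3085 for AG1478, Erlotinib and PD153035 in KO ras, 1060, 78 and 643 in KO minus WT in ras with the same inhibitors, 108 and 11 in the mean inhibitor effect WT ras minus KO ras and minus WT mock, and 1228 in the F test in WT ras. The higher share moved from 60.65 to 49.08 percent in KO minus WT in mock, from 36.91 to 48.3 percent in KO minus WT in ras with AG1478 (512 higher, 548 lower) and from 66.74 to 56.57 percent for Erlotinib in WT ras (495 higher, 380 lower). Median centring gave 3 in the mean inhibitor effect WT ras minus WT mock (1 higher, 2 lower).

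Fitting only the groups compared gave 17 in ras effect in WT, 5 in ras effect in KO, 0 in ras effect KO minus WT, 4 in KO minus WT in mock, 2 in KO minus WT in ras, 3, 50 and 14 for AG1478, Erlotinib and PD153035 in WT ras, 14, 0 and 382 in KO ras (limma), 235, 18 and 910 in KO minus WT in ras with them, 23 and 10 in the mean inhibitor effects, and 4 in the F test in WT ras. Array weights gave 94, 861, 231, 4900 and 2199 in the first 5 of these, 27, 6 and 293 for the inhibitors in WT mock, 991, 1640 and 790 in WT ras, 3360, 6636 and 8793 in KO ras, 1543, 2895 and 3435 in KO minus WT in ras with them, 3134 and 162 in the mean inhibitor effects, and 3931 and 7863 in the F tests in WT ras and KO ras; *Egfr* level was called in 1 comparison.

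Forward arrays only gave 1 in ras effect KO minus WT, 636 in KO minus WT in mock, 954 and 59 for AG1478 and PD153035 in WT ras, 238, 223 and 2561 in KO ras, 257 in KO minus WT in ras with PD153035, 385 and 13 in the mean inhibitor effects, and 280 in the F test in WT ras. No dye term gave 333 in KO minus WT in ras, 274 and 24 for AG1478 in WT ras and KO ras, 169 in KO minus WT in ras with Erlotinib, 16 in the mean inhibitor effect WT ras minus KO ras, and 280 in the F test in WT ras. Probes averaged by gene, which tests fewer, gave 4 in ras effect in WT, 58 in ras effect in KO, 281 in KO minus WT in ras, 303, 565 and 114 for the inhibitors in WT ras, 33, 9 and 683 in KO ras, 24 in the mean inhibitor effect WT ras minus KO ras, and 219 and 646 in the F tests. Complete probes gave 42 for AG1478 in KO ras. Keeping the repeat 1 arrays apart gave 673 in KO minus WT in mock, 2 for AG1478 in WT mock and 17 in the mean inhibitor effect WT ras minus WT mock.

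With sign and dye term by label, counts became 2285 for AG1478 in KO ras, 1677 in KO minus WT in ras with AG1478, 8 in the mean inhibitor effect WT ras minus KO ras and 4462 in the F test in KO ras, and *Egfr* level was called in 1 comparison. *Vegfa* in AG1478 in KO ras reversed to 0.29, as did Apbb1 in KO minus WT in ras with AG1478 (−0.0684), Dsg1a in KO minus WT in ras with AG1478 (−0.43), Itga6 in KO minus WT in ras with AG1478 (−0.0922), Pgk1 in KO minus WT in ras with AG1478 (−0.0886) and, in the same comparison, the basal (adjusted p = 0.126), Notch (adjusted p = 0.469) and TGF-beta (adjusted p = 0.469) lists. Dye term by label gave 40 for AG1478 in KO ras, and both disputed arrays left out 291 in KO minus WT in ras with AG1478.

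Samples share only a replicate number: 27 of 70 same-numbered pairs correlated over 0.1 (−0.656 to 0.531), and in 0 of 16 comparisons every pair did. The replicate block in place of the dye term gave 18 for AG1478 in KO ras, 1 for PD153035 in WT mock and 30 in the mean inhibitor effect WT ras minus KO ras, and moved no other count by over 1.5 times. With controls split, the profile correlation was 0.066. An estimated correlation left 14 list calls over the 19 comparisons.

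Leaving out 1 sample gave 34 to 57 in ras effect in WT, 41 to 282 in ras effect in KO, 1 to 50 in ras effect KO minus WT, 64 to 473 in KO minus WT in mock, 83 to 1008 in KO minus WT in ras, 0 to 1, 0 to 0 and 0 to 2 (limma) for AG1478, Erlotinib and PD153035 in WT mock, 129 to 961, 243 to 1523 and 55 to 359 in WT ras, 3 to 663, 0 to 397 and 375 to 2554 in KO ras, 341 to 891, 80 to 419 and 205 to 394 in KO minus WT in ras with them, 6 to 553 and 1 to 16 in the mean inhibitor effects, 0 to 0, 184 to 859 and 483 to 1496 in the F tests in WT mock, WT ras and KO ras, 86 to 107 list calls, 0 to 0 for *Egfr* level, and 0.386 to 0.540 for the profile correlation. Of 353 named gene results, 213 lost their call with run as a random block, 189 of 294 with only the groups compared, 73 with forward arrays only and 0 without a filter. Missing values limit the data: arrays lacked up to 3189 values, and changes of log2 1 were mostly missed in simulation.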

Other observations

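Averaged over the 3 inhibitors, cytokines and chemokines fell together in WT mock cells (0 of 22 called, 0 adjusted over the list alone; median −0.79, adjusted p = 6.97e-08; adjusted p = 0.00558 with an estimated correlation), although limma called 0 single probes (1452 at unadjusted p under 0.05). In WT ras the same average gave 4 of 22 called and 5 adjusted over the list alone (adjusted p = 0.0117; adjusted p = 0.463 with an estimated correlation). Among single genes of that average, *Cyp11b2*, aldosterone synthase (−2.09 ± 0.40, 0.00224), fell and *Emid1* (2.09 ± 0.44, 0.00571) rose.

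Same-group arrays of different runs were compared as values: run 2 minus run 1 called 105 probes, run 8 minus run 7 0 (limma), run 6 minus run 5 12, and run 5 minus run 3, with 1 array in run 5, 1514. Summed over the 19 comparisons of the design, lists were called 94 times at the preset correlation and 14 times with it estimated. Across genes, KO minus WT in mock and the mean inhibitor effect in WT mock correlated at 0.633 (0.580 simulated for 4 shared samples), and ras effect in WT and ras effect in KO at 0.099.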
